A study of Mus musculus with 9 samples.

How the data were processed

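RNA of 9 pooled samples of sorted mouse epithelial cells was measured on single-colour Agilent arrays, with 3 arrays for each of 3 groups taken from the sample titles. Labelling with Cy3 was done by Miltenyi Biotech, per the labels, and the arrays were read with Agilent Feature Extraction 10.5.1.1, per the file headers. The deposited processed signal of each spot is an intensity on a linear scale, background-subtracted and detrended by the scanner software with a surrogate value where the signal was not significant, per the file headers, and it was not yet normalized between arrays. The mean and local background intensities of each spot, also deposited, are raw per the file headers. The authors' deposited value table holds intensity as well. Set against the scanner files by feature number, each of its columns equalled the processed signal divided by the array's median over non-control spots, with a largest relative deviation of 2.37e-05. Its scale is thus linear, each column's median is 1, and genes were not centred. How the authors made that table is not given in the sources used here.

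Each array held 45018 spots, of which 43379 were not controls. Control spots and spots flagged as outliers by the scanner software were left out, and spots of the same probe were averaged, which gave 41174 probes. No spot was saturated (0 on each array). Probe accessions were matched without versions to a RefSeq table of assembly GRCm38.p6, used for names alone: 24375 probes matched and 16799 kept the name in the file. Of 28478 gene names, 17016 were RefSeq names. A gene was represented by the probe with the highest mean over the 9 arrays. Probe positions are those of the array's annotation on mm8, per the file headers.

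Values were log2 processed signal minus the array's 75th percentile over non-control probes. Genes were kept if their probe was well above background on all 3 arrays of at least 1 group, which left 19993 genes (13665 with RefSeq names). Linear models were fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), with group as the factor. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. The comparisons were MHCIIhi minus MHCIIlo, kidney minus the mean of the intestinal groups, and kidney minus each intestinal group. Gene lists, 35 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjusted p over the lists of a comparison. A gene was taken as above background in a group or on a side where any of its probes was well above background on at least 1 of its arrays. A list member was counted where it was above background on either side. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Replicates were independent pools of mice, per the labels. The p-values rest on a spread between arrays that was pooled over the groups. Within MHCIIhi that spread also holds slide and scan, as MHCIIhi 3 lay on another slide than MHCIIhi 1 and 2. The difference between MHCIIhi and MHCIIlo may likewise hold part of a slide difference.

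Genes named in the text followed a rule fixed before the data were examined. It took the markers of the gates (Epcam, Ptprc, H2-Ab1, H2-Aa, H2-Eb1 and Cd74) and the 6 largest differences per direction among called genes measured on at least 2 of 3 arrays in every group, with sides that did not overlap. It also took up to 4 genes per direction with the largest lower bound of the fold, and up to 4 called members of each list. Names that are only clones or predicted loci were passed over. The text gives a selection of these genes, and the results of some of them are not reported here.

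The fitting code was tested on simulated data in which some genes were changed by known amounts. Noise was drawn for each probe on its own, without a slide effect or correlation between genes. The shares below thus test the code and need not hold for the real data. For MHCIIhi minus MHCIIlo, over 19978 genes, 65.5% of changes of log2 size 1.5, 93.2% of size 2 and 93.0% of size 3 were called, with 0.0758% of unchanged genes. For kidney minus intestine, over 19981 genes, the shares were 83.1%, 90.6% and 98.7%, with 0.0354% of unchanged genes. For kidney minus MHCIIhi, over 19984 genes, they were 61.0%, 79.4% and 98.3%, with 0.0354%. For kidney minus MHCIIlo, over 19988 genes, they were 65.5%, 84.9% and 91.3%, with 0.0303%.

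Alternatives fixed before the data were examined were quantile normalization, scaling to the median of genes well above background on all arrays, normexp background correction with offset 50, the authors' value table, no filter on dim probes, a filter requiring all arrays, the mean of a gene's probes, a trend with robust prior, fits on the arrays of a comparison alone, the replicate number as a block, slide as a fixed or random block, other thresholds, and leaving out each array. Chosen after seeing the data were a filter on the groups of the comparison itself, a fit without MHCIIhi 3 and MHCIIlo 1, and camera with an estimated correlation within the slide.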

Results

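Gene expression was measured in epithelial cells sorted from C57BL/6 mice, in 9 samples that formed 3 groups of 3 independent replicates. Cells released from the small intestine with EDTA were sorted into a group with high surface Epcam and high surface MHC class II (MHCIIhi) and a group with intermediate levels of both (MHCIIlo). Cells freed from kidney with collagenase, dispase and DNase were sorted as Epcam-positive (kidney). Epcam is an adhesion molecule of epithelial cells, and MHC class II molecules present peptides to helper T cells. Every gate left out cells that stained for CD45, the common leukocyte surface protein, or for Fluorogold, used here to exclude dead cells. Each intestinal replicate pooled cells of 3 mice and each kidney replicate cells of 4 mice. Each sample was read on its own single-colour Agilent array. The 75th percentile of the processed signal was 320, 371 and 213 on the MHCIIhi arrays, 185, 121 and 100.6 on the MHCIIlo arrays, and 599, 663 and 769 on the kidney arrays. Spots well above background made up 64.7, 60.9 and 62.4% in MHCIIhi, 57.3, 56.1 and 51.0% in MHCIIlo, and 71.2, 73.2 and 72.9% in kidney. The number of arrays, 3 per group, limits the precision of every value. Levels are given as log2 signal minus the array's 75th percentile, as mean ± SD, and differences as log2 values ± SE with limma's Benjamini-Hochberg adjusted p.

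The first principal component held 79.1% of the variance and separated kidney from intestine. The second held 14.6% and separated MHCIIhi from MHCIIlo, with MHCIIhi 3 at -36.1 and MHCIIlo 1 at 36.5 lying closest to the other group. MHCIIhi 3 shared a slide and a scan with the 3 MHCIIlo arrays, whereas MHCIIhi 1 and 2 lay on another slide and the 3 kidney arrays on a slide of their own.

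The intestinal comparison asked how epithelial cells with high surface MHC class II differed from those with intermediate levels. Transcripts of the proteins used for the gate were not higher in MHCIIhi. Epcam stood at 5.04 ± 0.24 in MHCIIhi and 5.30 ± 0.21 in MHCIIlo (SD, n = 3 each), a difference of -0.26 ± 0.30 (limma adjusted p = 0.480). H2-Ab1, a beta chain of MHC class II, stood at 6.59 ± 0.17 and 7.13 ± 0.35, a difference of -0.55 ± 0.22 (limma adjusted p = 0.0634). H2-Aa and H2-Eb1, an alpha and a beta chain, differed by -0.55 ± 0.29 (adjusted p = 0.141) and -0.47 ± 0.20 (adjusted p = 0.0810). Cd74, the invariant chain that escorts class II molecules to endosomes, was 2.14-fold lower in MHCIIhi (6.37 ± 0.06 against 7.47 ± 0.06, SD, n = 3 each; adjusted p = 0.00627 in limma). Ciita, the transactivator of class II genes, and H2-DMb1, part of the peptide exchange factor, were also lower, by -1.35 ± 0.23 (adjusted p = 0.00257) and -1.40 ± 0.21 (adjusted p = 0.00177). For these 3 genes each MHCIIhi array lay below each MHCIIlo array.

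Of 10 class II presentation genes above background, 0 were higher in MHCIIhi and 3 were lower, both over all genes and adjusted over the list alone. At an unadjusted p under 0.05, limma gave 0 higher and 6 lower. The list median was -0.65, or -0.42 relative to the median of all genes, which was itself -0.24, and camera's adjusted p was 0.0913. Without MHCIIlo 3 the list median was -0.84 with camera's adjusted p at 0.0167, in a range of 0.0167 to 0.888 over the alternatives. The median was -0.28 with quantile normalization and -0.40 with normexp. Cd74 fell short of the size threshold with quantile normalization (-0.75) and with normexp (-0.84), and H2-DMb1 did with quantile normalization (-0.96). Of 20 class I presentation genes, 0 were higher and 3 lower, in both counts (0 and 11 at unadjusted p under 0.05 in limma). Ptprc, which encodes CD45, stood at -2.43 ± 1.003 in MHCIIhi and -1.50 ± 0.33 in MHCIIlo (SD, n = 3 each), a difference of -0.93 ± 0.44 (limma adjusted p = 0.107). Without MHCIIhi 1, Ptprc passed both thresholds (-1.37, adjusted p = 0.0333, in a range of 0.0257 to 0.475 over the alternatives). Surface protein, on which cells were sorted, and transcript are different measurements. The Epcam probe maps to chromosome 17, 87557958 to 87558786, the H2-Ab1 probe to chromosome 17, 33877309 to 33877368, and the Cd74 probe to chromosome 18, 60937790 to 60937847, on mm8 as in the array's annotation.

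**Figure D1:**
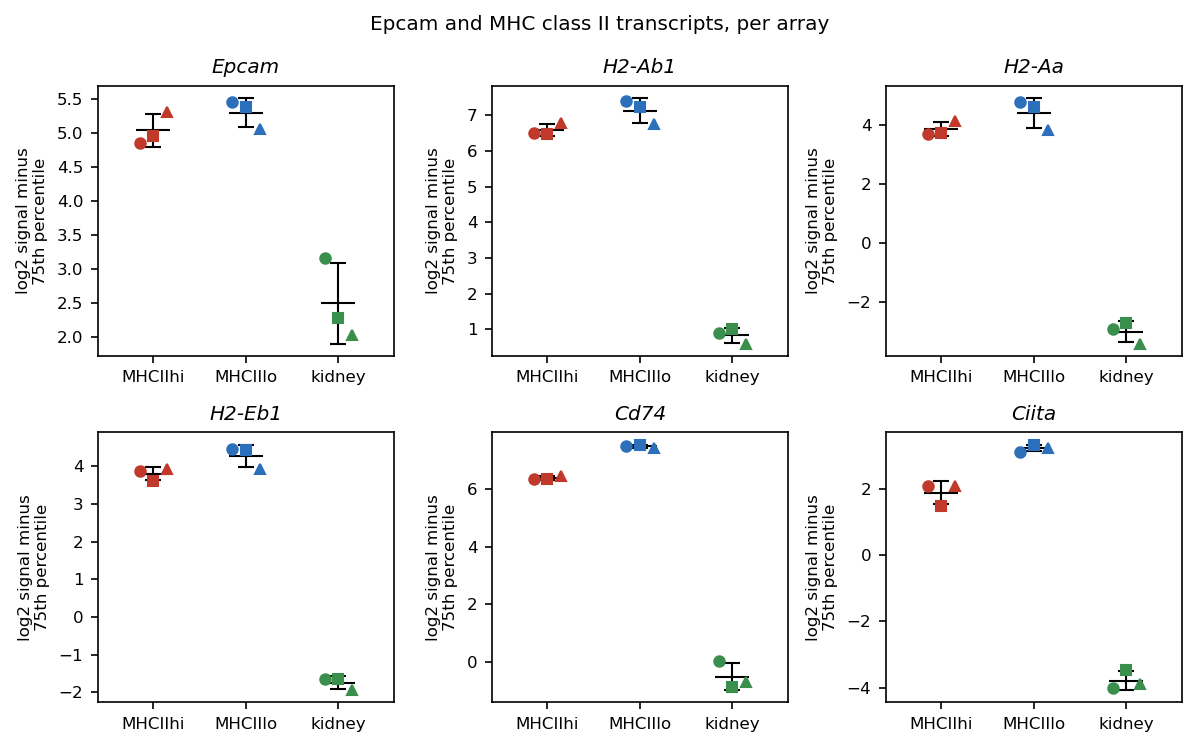
Log2 signal minus the array's 75th percentile (vertical axis) of Epcam and 5 MHC class II presentation genes in MHCIIhi, MHCIIlo and kidney, where circles, squares and triangles are replicates 1, 2 and 3, long bars are means and whiskers are SD. Cd74 averaged 6.37 in MHCIIhi, 7.47 in MHCIIlo and -0.50 in kidney.

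Genes of dividing cells, stem cells, Paneth cells and goblet cells were higher in MHCIIhi. Cdk1, the kinase that drives entry into mitosis, stood at 0.93 ± 0.62 in MHCIIhi and -4.17 ± 1.42 in MHCIIlo (SD, n = 3 each; limma adjusted p = 0.000732). As 1 of 3 MHCIIlo arrays measured it well above background, it was at least 19.1-fold higher. Such a bound sets the bright group's mean against, on each dim array that did not measure the probe, the higher of the probe's own signal and the lowest signal among probes well above background. All 30 cell cycle genes above background were higher and 0 were lower (0 at unadjusted p under 0.05 in limma), with the same counts adjusted over the list alone. Other examples were Bub1, a spindle checkpoint kinase (at least 15.0-fold, measured on 1 of 3 MHCIIlo arrays), Mcm3, part of the replicative helicase (4.47 ± 0.42), and Pola1, the catalytic subunit of DNA polymerase alpha (at least 22.1-fold, measured on 2 of 3 MHCIIlo arrays). The cell cycle median was 3.74, or 3.98 relative to all genes and 3.70 with the bounded gene at its bound. Camera's adjusted p was 1.14e-18, and the call was lost at adjusted p = 0.736 with an estimated correlation.

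Of 24 intestinal stem cell genes, 18 were higher and 1 was lower, also adjusted over the list alone. Lgr5, a receptor that marks stem cells at the crypt base, stood at 1.103 ± 0.83 in MHCIIhi and -3.74 ± 0.71 in MHCIIlo (SD, n = 3 each; limma adjusted p = 0.000271). It was at least 24.3-fold higher, with 1 of 3 MHCIIlo arrays measuring it. Olfm4, a secreted glycoprotein of the same cells, was 27.6-fold higher (2.44 ± 0.56 against -2.35 ± 0.81, SD, n = 3 each; limma adjusted p = 0.000232). Myb, a transcription factor, differed by 4.06 ± 0.49 (4.66 without MHCIIlo 1), while Msi1, an RNA-binding protein, was the member that was lower (-1.96 ± 0.38). The list median was 2.79 relative to all genes (2.55, and 2.40 with bounded genes at their bound). Camera's adjusted p was 9.95e-10, and adjusted p = 0.736 with an estimated correlation.

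Of 14 Paneth cell genes, 12 were higher and 0 lower (13 higher adjusted over the list alone; 0 lower at unadjusted p under 0.05 in limma). Mmp7, a metalloprotease that activates defensins, was higher by 2.80 ± 0.58 (limma adjusted p = 0.00606, and 2.12 without MHCIIlo 2). The transcript of the phospholipase gene Pla2g2a was higher by 3.22 ± 0.58. Kit, a receptor tyrosine kinase, was at least 8.13-fold higher with 1 of 3 MHCIIlo arrays measuring it. The Paneth median was 2.16 relative to all genes (camera adjusted p = 3.83e-05; adjusted p = 0.736 with an estimated correlation). Of 20 goblet cell genes, 15 were higher and 0 lower, also adjusted over the list alone (1 lower at unadjusted p under 0.05 in limma). Agr2, a disulfide isomerase needed for mucin production, stood at 7.33 ± 0.31 in MHCIIhi and 4.95 ± 0.89 in MHCIIlo (SD, n = 3 each), 5.21-fold apart (limma adjusted p = 0.00275). Spdef and Creb3l4, transcription factors of secretory cells, were higher by 2.23 ± 0.31 and 2.62 ± 0.44. The goblet median was 2.13 relative to all genes (camera adjusted p = 5.79e-06; adjusted p = 0.736 with an estimated correlation).

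Absorptive enterocyte genes and xenobiotic metabolism genes were lower in MHCIIhi, and so were markers of lymphocytes and fibroblasts. Of 30 enterocyte genes, 26 were lower and 0 higher (27 lower adjusted over the list alone; 0 higher at unadjusted p under 0.05 in limma). Rbp2, an intracellular retinol-binding protein, was 8.06-fold lower (2.76 ± 1.22 against 5.78 ± 1.34, SD, n = 3 each; limma adjusted p = 0.0104; -3.77 without MHCIIlo 1 and -3.71 without MHCIIhi 3), and Khk, the first enzyme of fructose breakdown, was lower by -2.50 ± 0.60. Fabp1, a fatty acid-binding protein, differed by -2.54 ± 0.76 (limma adjusted p = 0.0239). Its call was lost without MHCIIhi 2 (-2.17), MHCIIlo 2 (-2.29) or MHCIIlo 3 (-2.20), and the difference was -3.13 without MHCIIlo 1. The enterocyte median was -1.49 relative to all genes (camera adjusted p = 5.79e-06; adjusted p = 0.821 with an estimated correlation). Of 24 xenobiotic metabolism genes, 15 were lower and 0 higher (16 lower adjusted over the list alone; 0 higher at unadjusted p under 0.05 in limma), among them the cytochrome P450 gene Cyp2d26 (-2.18 ± 0.49) and the glutathione transferase gene Gsta1 (-1.96 ± 0.33). Their median was -1.01 relative to all genes (camera adjusted p = 0.000757; adjusted p = 0.764 with an estimated correlation), and without that shift -1.25, or -1.22 with the bounded gene at its bound. Of 24 cholesterol synthesis genes, 3 were lower and 0 higher, also adjusted over the list alone (12 and 0 at unadjusted p under 0.05 in limma). Their median was -0.36 relative to all genes (camera adjusted p = 0.0104; adjusted p = 0.821 with an estimated correlation), and the call was lost without MHCIIhi 1 (median -0.38, adjusted p = 0.0621) or MHCIIlo 1 (adjusted p = 0.0976). It was also lost with normexp (-0.31, adjusted p = 0.861), quantile normalization (-0.35, adjusted p = 0.114) and no filter on dim probes (adjusted p = 0.0577), in a range of 0.00236 to 0.888 over the alternatives.

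Of 9 B cell and plasma cell genes, 4 were lower in MHCIIhi and 0 higher, also adjusted over the list alone (0 higher at unadjusted p under 0.05 in limma). Jchain, which joins immunoglobulin chains into polymers, stood at -0.15 ± 0.90 in MHCIIhi and 4.83 ± 0.43 in MHCIIlo (SD, n = 3 each), 31.5-fold apart (limma adjusted p = 0.000268). Mzb1, a chaperone of antibody-secreting cells, was at least 18.6-fold lower with 1 of 3 MHCIIhi arrays measuring it, and Pou2af1, a B cell coactivator, by -3.11 ± 0.32. The list median was -0.74 relative to all genes (camera adjusted p = 0.0242; adjusted p = 0.736 with an estimated correlation), and its call was lost without MHCIIhi 3 (adjusted p = 0.0789) or MHCIIlo 1 (adjusted p = 0.0786) and with genes well above background on all arrays only (adjusted p = 0.155), in a range of 0.00244 to 0.747 over the alternatives. Of 16 genes with names starting with Igh, Igk or Igl, a set outside the fixed lists, 15 were lower in MHCIIhi and 0 higher. Their median was -4.94, or -4.52 with unmeasured arrays at their bound. Immunoglobulin segments have near-identical copies, so single names are uncertain. Of 19 T cell and intraepithelial lymphocyte genes, 12 were lower and 1 higher, also adjusted over the list alone, among them the protease gene Gzma (-1.76 ± 0.38) and the surface protein gene Cd7 (-1.66 ± 0.35). Their median was -1.20 relative to all genes (camera adjusted p = 0.00397; adjusted p = 0.821 with an estimated correlation). With genes well above background on all arrays only, the T cell list was not called (adjusted p = 0.155, in a range of 0.000115 to 0.888 over the alternatives).

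Of 17 macrophage and dendritic cell genes, 6 were lower in MHCIIhi and 2 higher (7 and 2 adjusted over the list alone), with the complement gene C1qb at -2.17 ± 0.39 (-1.44 within the shared slide, where the call was lost). The list median was -0.80 (-0.34 within the slide), and camera did not call it (adjusted p = 0.244). B cells, macrophages and dendritic cells also express class II genes. Of 15 fibroblast and smooth muscle genes above background, 8 were lower in MHCIIhi and 0 higher (9 lower adjusted over the list alone; 0 higher at unadjusted p under 0.05 in limma). Dcn, the matrix proteoglycan decorin, differed by -4.90 ± 1.01 (-3.63 ± 0.90 against 1.27 ± 2.37, SD, n = 3 each; limma adjusted p = 0.00578). Col3a1, a fibrillar collagen, was not well above background on any MHCIIhi array and was at least 6.00-fold lower there. These values leaned on MHCIIlo 3, without which Dcn differed by -3.57 (-5.81 without MHCIIlo 2), the bound for Col3a1 was 3.64-fold and the list median was -0.85 in place of -1.41 over all members tested. The list median was -1.27 relative to all genes (-1.50, and -1.07 with bounded genes at their bound), with camera adjusted p = 0.00425 and adjusted p = 0.821 with an estimated correlation.

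**Figure D2:**
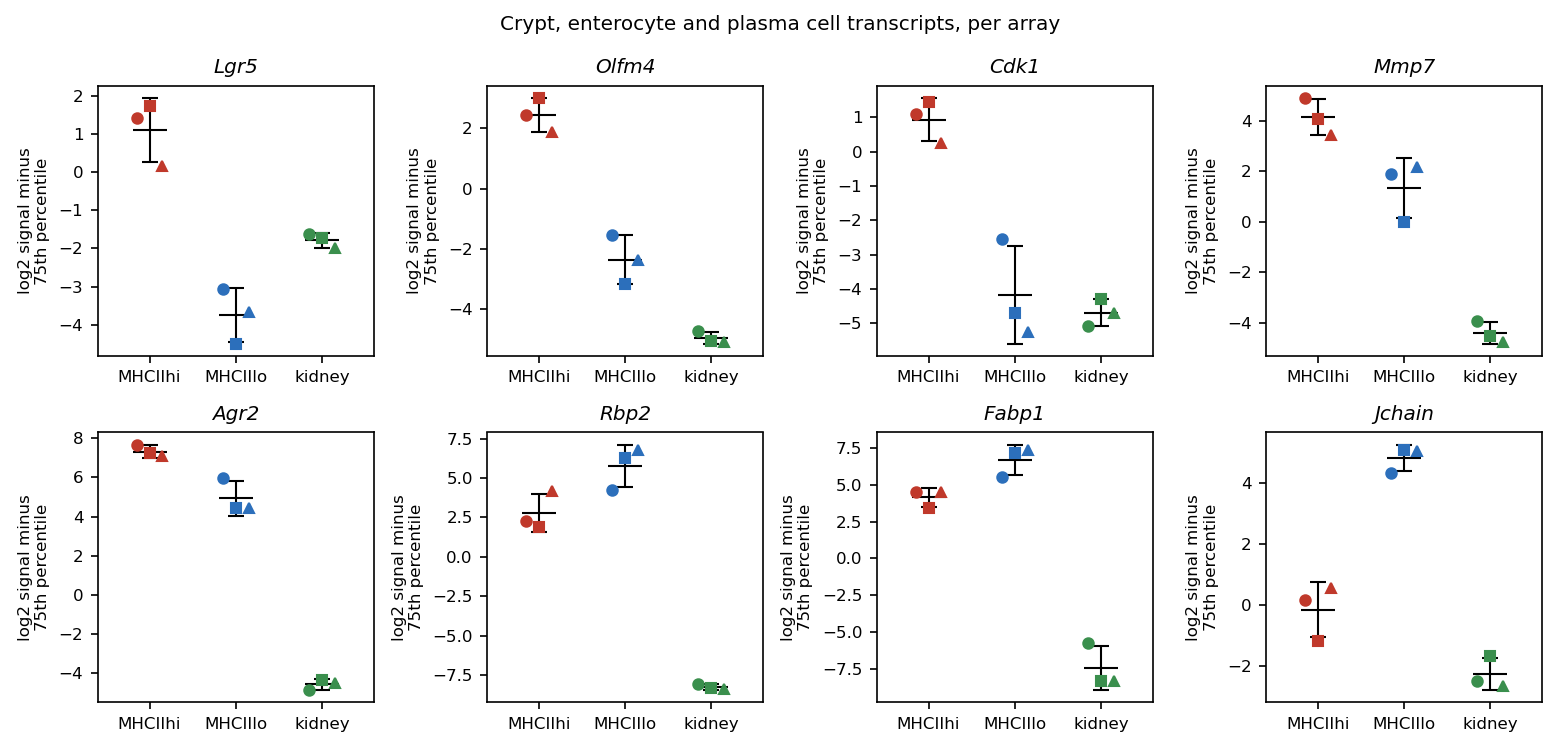
Log2 signal minus the array's 75th percentile (vertical axis) of 8 transcripts in MHCIIhi, MHCIIlo and kidney, where circles, squares and triangles are replicates 1, 2 and 3, long bars are means and whiskers are SD. Lgr5 averaged 1.103 in MHCIIhi and -3.74 in MHCIIlo, and Jchain -0.15 and 4.83.

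In all, limma called 6197 of 19993 genes between MHCIIhi and MHCIIlo at an adjusted p below 0.05 and an absolute log2 difference of at least 1, of which 2978 were higher and 3219 lower in MHCIIhi. Both groups measured 5092 of these above background, while 571 of the higher genes were above background in MHCIIhi alone and 97 of the lower genes in MHCIIlo alone. A further 13 genes called lower were above background in MHCIIhi alone. For 424 called genes, 423 of them lower, neither group measured the gene above background, so their differences are not between measured signals. The excess of lower genes was not kept when such genes left. A filter on the groups of the comparison, chosen after seeing the data, gave 5575 genes, 51.4% of them higher. The fit on the arrays of the comparison alone gave 5441, 51.5% of them higher, against 48.1% in the main fit. The lowest signal among probes well above background was -4.35 to -3.43 on the MHCIIlo arrays and -5.37 to -4.45 on the MHCIIhi arrays. Over all 19993 genes tested, called or not, the arrays of the groups did not overlap for 11278 (56.4%), where chance gives 10%. With slide as a block the comparison rested on MHCIIhi 3 against the 3 MHCIIlo arrays of the same slide, which is also the comparison within that slide, where the lone MHCIIhi array has no spread of its own and is assumed to vary like the arrays of the other groups, whose pooled spread was used. Limma then called 1683 genes (1380 higher, 303 lower), against 4619 with slide as a random block. All 6197 genes kept their sign there, and 1568 of them were called, but MHCIIhi 3 enters both fits. Without MHCIIhi 3 and MHCIIlo 1, an alternative chosen after seeing the data, 9367 genes were called, and normexp gave 2951.

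Calls within the shared slide rest on MHCIIhi 3 alone against the MHCIIlo arrays, with the spread taken from the other arrays. As MHCIIhi 3 also enters the full fit, a call kept there is not separate support. Within that slide, the list medians were 3.04 for cell cycle, 2.11 for stem cell, 1.87 for Paneth and 1.77 for goblet genes. They were -0.95 for enterocyte, -0.86 for xenobiotic metabolism, -1.06 for T cell, -0.74 for B cell and plasma cell, -1.43 for fibroblast, -0.25 for cholesterol synthesis, -0.35 for class II and -0.45 for class I presentation genes. Camera called each of these lists there except class II (adjusted p = 0.0661) and cholesterol synthesis (adjusted p = 0.0641), and class I was called there alone (adjusted p = 0.0196, against 0.138 over all arrays). None was called within the slide with an estimated correlation, an alternative chosen after seeing the data (adjusted p = 0.747 with an estimated correlation for stem cell to adjusted p = 0.888 for class I genes). Genes that kept their call within the slide were Cdk1 (4.41), Bub1 (4.27), Mcm3 (4.02), Pola1 (4.11), Lgr5 (3.90), Olfm4 (4.22), Myb (3.58), Kit (2.54), Spdef (2.02), H2-DMb1 (-1.39), Jchain (-4.28), Mzb1 (-3.88) and Pou2af1 (-2.70). Those that lost it, with 1 array against 3, were Cd74 (-1.03), Ciita (-1.14), Msi1 (-1.04), Mmp7 (2.12), Pla2g2a (2.42), Agr2 (2.13), Creb3l4 (2.13), Rbp2 (-1.62), Khk (-1.66), Fabp1 (-2.20), Cyp2d26 (-1.30), Gsta1 (-1.83), Gzma (-1.37), Cd7 (-1.06), Dcn (-4.78) and Col3a1 (-3.34). Epcam, H2-Ab1, H2-Aa, H2-Eb1 and Ptprc differed by 0.01, -0.36, -0.28, -0.34 and -0.72 within the slide and were not called.

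**Figure D3:**
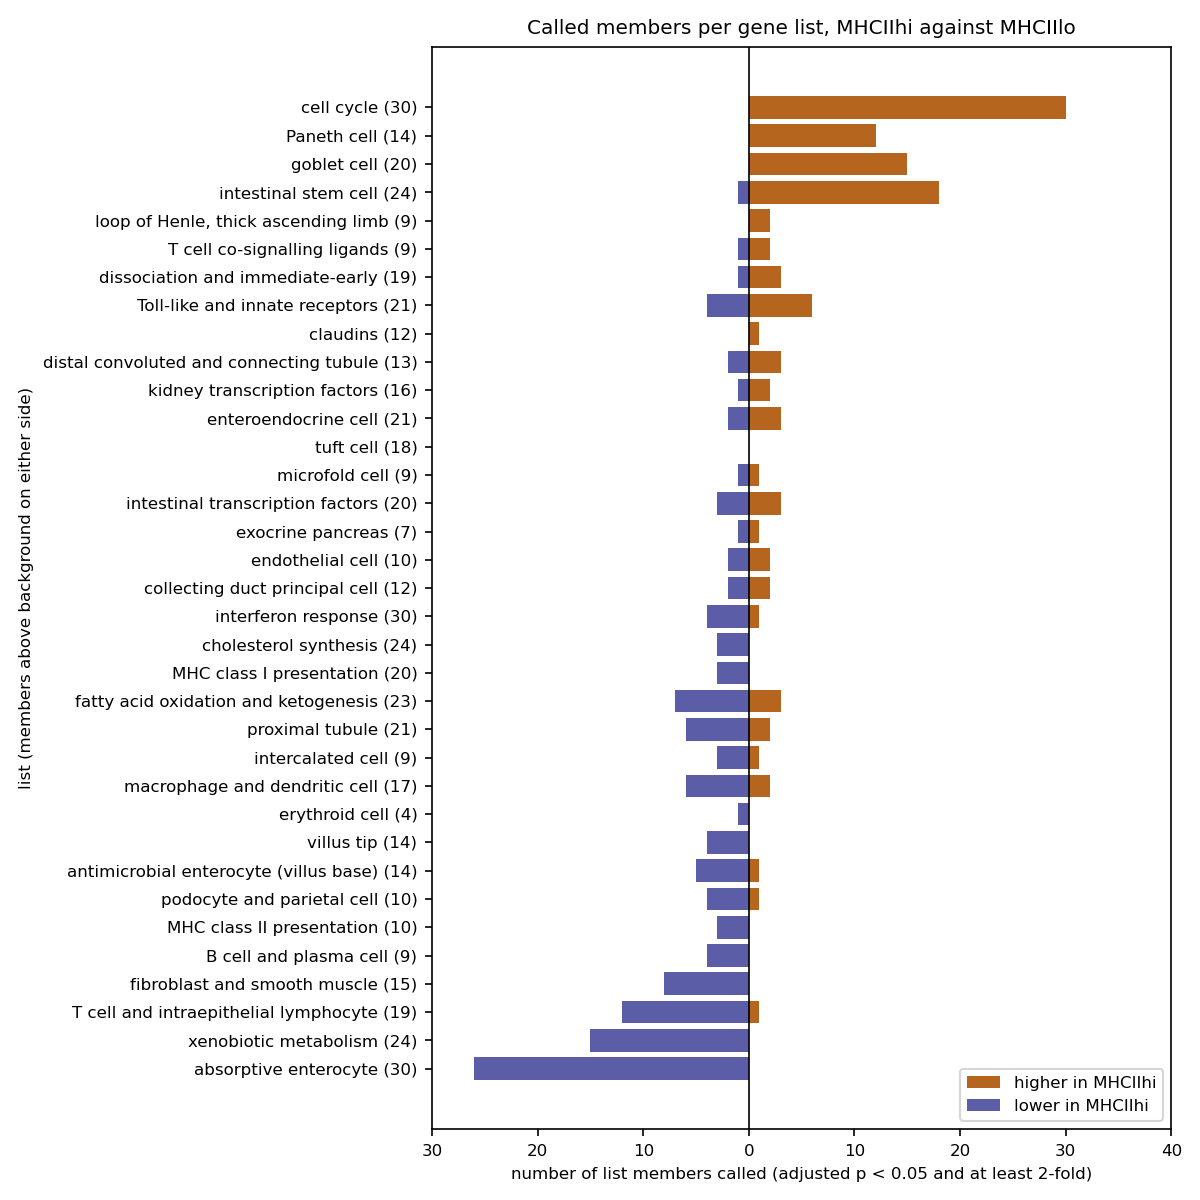
Number of members of each gene list called higher (right) or lower (left) in MHCIIhi than in MHCIIlo by limma (horizontal axis, bars from 0), with the number of members above background in either group in parentheses. All 30 cell cycle genes were higher and 26 of 30 enterocyte genes lower.

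The organ comparison set kidney against the mean of the intestinal groups. Markers of tubule segments from the loop of Henle to the collecting duct were higher in kidney. Umod, which encodes uromodulin of the thick ascending limb, stood at 8.92 ± 0.05 in kidney (SD, n = 3), was not well above background on any intestinal array and was at least 10650-fold higher (limma adjusted p = 1.27e-09). All 17 thick ascending limb genes were higher, also adjusted over the list alone, among them the potassium channel gene Kcnj1 at least 2317-fold. All 20 intercalated cell genes were higher, also adjusted over the list alone. Examples were the ammonia transporter gene Rhcg (at least 2641-fold), the proton pump gene Atp6v1g3 (at least 883-fold, or 1561-fold without kidney 1) and Slc26a4, the anion exchanger pendrin (at least 950-fold; measured on 2 of 3 MHCIIlo arrays; limma adjusted p = 2.91e-08). Medians were 8.73 and 8.26 for these lists, or 6.79 and 6.65 with bounded genes at their bound. Camera's adjusted p was 3.11e-09 and 6.40e-11, and adjusted p = 0.260 and adjusted p = 0.188 with an estimated correlation.

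Of 18 distal convoluted and connecting tubule genes, 14 were higher and 1 lower, also adjusted over the list alone, including Calb1, a calcium-binding protein (at least 2407-fold), and Kl, the FGF23 co-receptor (at least 1068-fold). Of 19 collecting duct principal cell genes, 17 were higher and 2 lower, also adjusted over the list alone. Fxyd4, a regulator of the sodium pump, was at least 1556-fold higher and Scnn1g, a subunit of the epithelial sodium channel, at least 339.8-fold, while the keratin gene Krt8 was lower (-4.76 ± 0.16). Medians were 5.94 and 6.10, or 4.64 and 6.06 at the bound, with camera adjusted p = 1.13e-06 and 1.04e-06, and adjusted p = 0.260 and adjusted p = 0.186 with an estimated correlation. Of 28 proximal tubule genes, 18 were higher and 5 lower, also adjusted over the list alone, from the aspartic protease gene Napsa (at least 148-fold higher, or 54.7-fold without kidney 1, 255-fold without kidney 2 and 231-fold without kidney 3) to the sulfate transporter gene Slc13a1 (-4.60 ± 0.45). The median was 2.13, or 1.82 at the bound (camera adjusted p = 0.00977; adjusted p = 0.415 with an estimated correlation). With genes well above background on all arrays only, the proximal tubule median was -0.63 and the list was not called.

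Endothelial markers were higher in kidney beside the tubule genes. Of 18 endothelial genes, 17 were higher and 0 lower, also adjusted over the list alone (1 lower at unadjusted p under 0.05 in limma), with a median of 7.00, or 5.49 at the bound (camera adjusted p = 2.65e-07; adjusted p = 0.260 with an estimated correlation). Emcn, a vascular sialoglycoprotein, stood at 4.30 ± 0.65 in kidney (SD, n = 3) and was at least 432-fold higher, and Kdr, a VEGF receptor, stood at 3.10 ± 0.58 and was at least 188-fold higher. With genes well above background on all arrays only, the endothelial median was 1.89 and the list was not called (adjusted p = 0.0567, in a range of 1.03e-10 to 0.260 over the alternatives). Of 25 kidney transcription factor genes, 21 were higher and 1 lower, also adjusted over the list alone, with Hoxd8 at least 202-fold and the nuclear receptor gene Esrrb at least 79.3-fold higher and Osr2 lower (-3.17 ± 0.15). The median was 3.69, or 2.39 at the bound (camera adjusted p = 1.13e-06; adjusted p = 0.260 with an estimated correlation).

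Enterocyte, goblet, antimicrobial and enteroendocrine genes and intestinal transcription factor genes were lower in kidney. Fabp2, the intestinal fatty acid-binding protein, stood at 9.37 ± 0.61 in MHCIIhi, 10.88 ± 0.30 in MHCIIlo and -4.03 ± 0.24 in kidney (SD, n = 3 each), a difference of -14.15 ± 0.27 (limma adjusted p = 2.51e-09). Of 30 enterocyte genes, 29 were lower in kidney and 0 higher, also adjusted over the list alone (0 higher at unadjusted p under 0.05 in limma), including the apolipoprotein gene Apoa1 (at least 11620-fold) and Sis, sucrase-isomaltase (at least 4689-fold). Of 20 goblet cell genes, 18 were lower and 2 higher, with Tff3, a mucus-stabilising peptide, at least 15450-fold lower and the kallikrein gene Klk1 higher (6.24 ± 0.26). Of 14 antimicrobial enterocyte genes, 13 were lower and 1 higher, with the lectin gene Reg3b at least 58810-fold lower. Of 21 enteroendocrine genes, 18 were lower and 2 higher, with the granule protein gene Chga at least 755-fold lower. Of 20 intestinal transcription factor genes, 19 were lower and 0 higher (0 at unadjusted p under 0.05 in limma), with the homeobox genes Cdx2 and Isx at least 1306-fold and at least 1507-fold lower. Counts adjusted over the list alone were the same for these 4 lists. Medians ran from -7.43 for goblet to -5.52 for enteroendocrine genes (-4.43 at the bound), with camera adjusted p from 2.91e-11 for enterocyte to 2.18e-06 for enteroendocrine genes. With an estimated correlation none of the 5 lists was called, with adjusted p = 0.186 for the transcription factor and antimicrobial lists and adjusted p = 0.260 with an estimated correlation for the others.

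Antigen presentation, cholesterol synthesis and cell cycle genes were also lower in kidney. All 10 class II presentation genes were lower and 0 higher (0 at unadjusted p under 0.05 in limma), also adjusted over the list alone, with Cd74 171-fold lower (-7.42 ± 0.20, limma adjusted p = 1.16e-08), H2-Ab1 65.4-fold and Ciita 80.4-fold. The list median was -5.91 (camera adjusted p = 1.04e-06; adjusted p = 0.216 with an estimated correlation). Of 20 class I presentation genes, 13 were lower and 0 higher (0 at unadjusted p under 0.05 in limma), also adjusted over the list alone, including Psmb10, an immunoproteasome subunit (-3.77 ± 0.14), with a median of -1.85 (camera adjusted p = 2.41e-05; adjusted p = 0.260 with an estimated correlation). Of 24 cholesterol synthesis genes, 21 were lower and 0 higher (0 at unadjusted p under 0.05 in limma), also adjusted over the list alone, with a median of -1.83 (camera adjusted p = 2.39e-07; adjusted p = 0.290 with an estimated correlation). Of 30 cell cycle genes, 23 were lower and 0 higher (0 at unadjusted p under 0.05 in limma), also adjusted over the list alone, including Top2a, a DNA topoisomerase (-4.51 ± 0.40), with a median of -3.06 (camera adjusted p = 1.60e-06; adjusted p = 0.418 with an estimated correlation). Against MHCIIhi alone all 30 were lower in kidney (median -4.81), whereas against MHCIIlo alone 15 were lower and 5 higher (median -1.40).

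Epcam itself was 6.39-fold lower in kidney (2.49 ± 0.59, SD, n = 3; limma adjusted p = 1.69e-05). Ptprc stood at -0.98 ± 0.20 in kidney (SD, n = 3), a difference of 0.99 ± 0.38 (limma adjusted p = 0.0424) that lay under the size threshold, and 1 of 2 other Ptprc probes above background on at least 1 array differed in the opposite direction. Ptprc passed both thresholds with median scaling (1.19) and without MHCIIhi 1 (1.21), MHCIIhi 3 (1.04) or MHCIIlo 2 (1.07). Lymphoid markers were lower in kidney. Of 9 B cell and plasma cell genes, 8 were lower and 0 higher (0 at unadjusted p under 0.05 in limma), and of 19 T cell genes, 11 were lower and 2 higher, with the same counts adjusted over the list alone. Jchain differed by -4.60 ± 0.40 and Gzma was at least 115-fold lower. Medians were -2.94 for the B cell list, or -2.77 at the bound (camera adjusted p = 0.00281; adjusted p = 0.260 with an estimated correlation), and -1.54 for the T cell list (camera adjusted p = 0.00468; adjusted p = 0.438 with an estimated correlation). With genes well above background on all arrays only, neither list was called: the medians were -1.56 for the B cell list (adjusted p = 0.178, in a range of 0.00118 to 0.260 over the alternatives) and -0.83 for the T cell list (adjusted p = 0.522, in a range of 0.00109 to 0.522). The Umod probe maps to chromosome 7, 119254164 to 119254223, the Fabp2 probe to chromosome 3, 122891380 to 122891439, and the Cdx2 probe to chromosome 5, 147611320 to 147611379, on mm8.

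**Figure D4:**
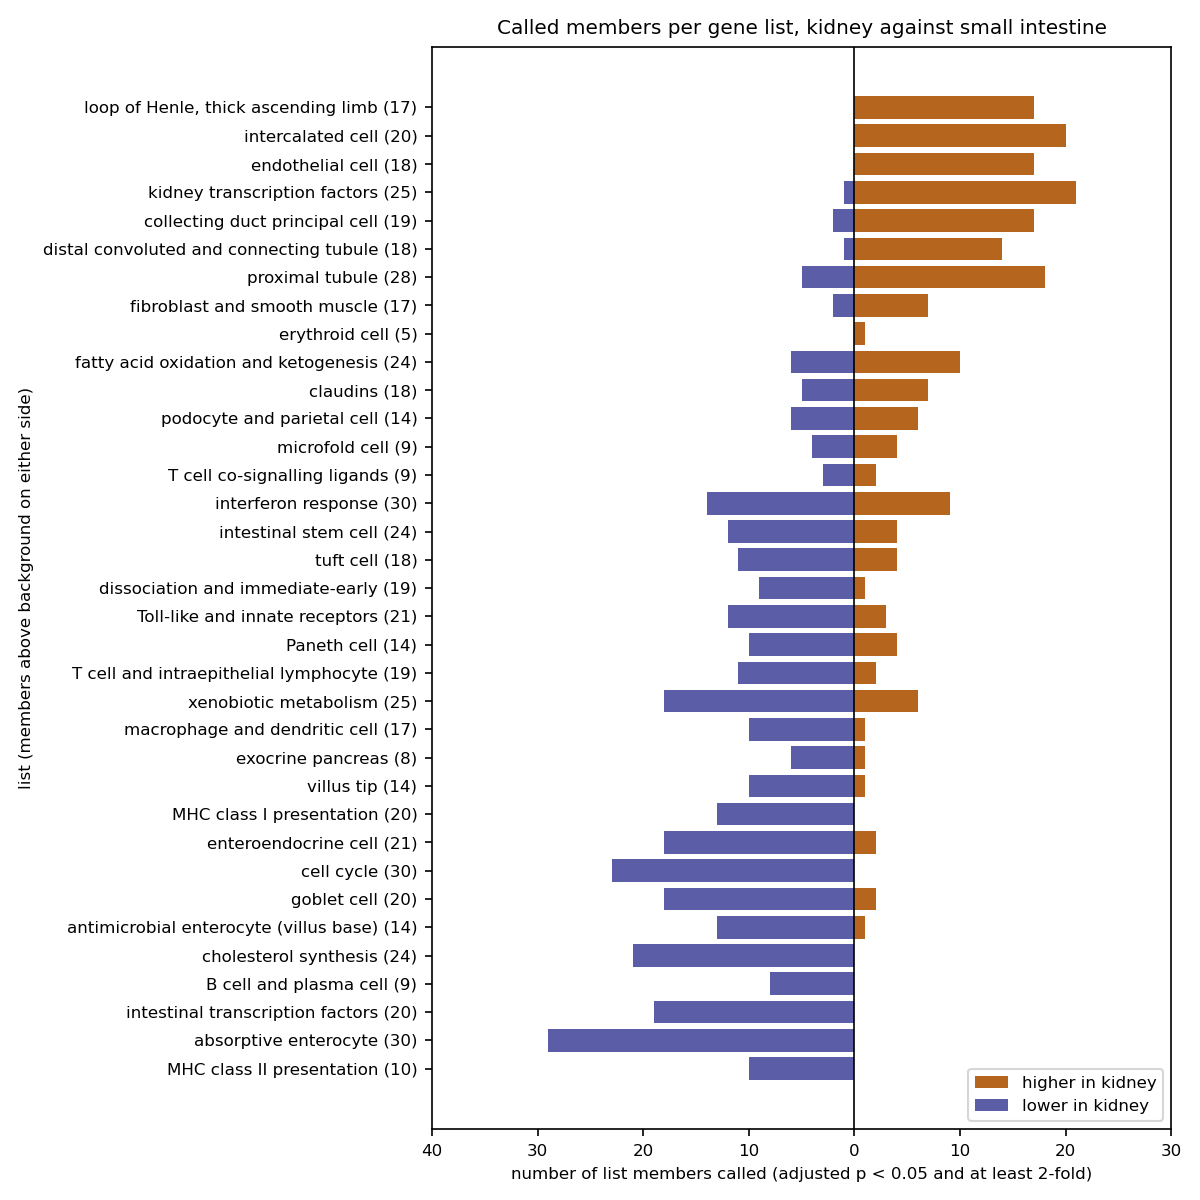
Number of members of each gene list called higher (right) or lower (left) in kidney than in the mean of the intestinal groups by limma (horizontal axis, bars from 0), with the number of members above background on either side in parentheses. All 20 intercalated cell genes were higher and all 10 class II presentation genes lower in kidney.

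Limma called 10432 of 19993 genes between kidney and intestine, 5481 higher and 4951 lower in kidney (52.5% higher). Both sides measured 8459 of them, 1543 were above background in kidney alone and 430 in intestine alone. Over all genes tested, the arrays of kidney and intestine did not overlap for 11587 (58.0%), where chance gives 2.38%. With normexp 30.0% of the called genes were higher in kidney. Kidney differed from MHCIIhi in 9681 genes (5120 higher, 4561 lower) and from MHCIIlo in 11516 genes (5950 higher, 5566 lower), and with normexp the share higher in kidney was 40.2% against 52.9% and 27.3% against 51.7%. The kidney arrays lay on a slide of their own. Kidney cells were freed with collagenase, dispase and DNase, and intestinal cells with EDTA. Slide, release of the cells and organ thus cannot be told apart.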

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

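Only the fit without MHCIIhi 3 and MHCIIlo 1, the dim-probe filter per comparison and the estimated correlation within the slide were chosen after seeing the data. The number of called genes between MHCIIhi and MHCIIlo (6197) was 2951 with normexp, 4024 with genes well above background on all arrays, 1683 with slide as a fixed block or within the shared slide, 10014 with the adjusted p alone, 1355 with adjusted p below 0.01 and an absolute log2 difference of at least 2, and 9367 without MHCIIhi 3 and MHCIIlo 1. For kidney against intestine (10432) the count was 16300 with no filter on dim probes, 5957 with the all-arrays filter and 5700 with the stricter threshold. For kidney against MHCIIhi (9681) it was 5444 and 5161 with the latter pair, and for kidney against MHCIIlo (11516) 17741, 7019 and 6488. Over the 2 main comparisons camera called 35 lists, 23 with the all-arrays filter and 0 with an estimated correlation, where 1 and 6 lists had an unadjusted p under 0.05. Fewer genes are tested under the stricter filter and fewer arrays enter within the slide; for the other changes the cause was not tested. Leaving out each array in turn gave 4271 (without MHCIIhi 2) to 8338 (without MHCIIhi 3) genes between MHCIIhi and MHCIIlo, 10188 to 10643 for kidney against intestine, 9281 to 9765 against MHCIIhi, 11175 to 11747 against MHCIIlo, 34 to 37 lists, and -0.84 (without MHCIIlo 3, where camera's adjusted p was 0.0167) to -0.50 for the class II list median. The all-gene median of MHCIIhi minus MHCIIlo, -0.24, was -0.07 with quantile normalization and -0.50 with normexp. For kidney against intestine, 0.00, it was 0.20 with median scaling, -0.47 with normexp and -0.28 with the authors' value table. Values turned sign with normexp for Tnfsf9 (-0.12), Cd276 (-0.37), Pax4 (-0.39), Egfl7 (-0.17), Egf (-0.61) and Ppp1r1a (-0.23) between the intestinal groups, and for Txk (-0.0567) and Tlr4 (-0.35) in kidney. Cyp4a10 turned with the mean of probes (1.06), and the proximal tubule list with the all-arrays filter (-0.63). Of 3383 other values of 138 genes between the intestinal groups, 2995 kept direction and call, 377 lost the call, 1 gained it and 4 uncalled values changed sign. Even so, 97 of these 138 genes lost their call in at least 1 alternative. The 138 include Epcam, Ptprc, H2-Ab1, H2-Aa and H2-Eb1, which were not called in the main fit. Camera's estimated correlation leaves gene values as they are, so its 138 values were bound to be kept. Of 2996 values of 147 genes in kidney, 2982 kept both, 7 lost and 4 gained the call, and 7 genes lost it in at least 1 alternative. Of 884 and 735 list values, 797 and 669 kept both, 32 and 43 lost and 13 and 12 gained the call. In the main fit camera had called 10 of these 34 and 25 of these 35 lists, and each of those called lost its call in at least 1 alternative. With the replicate number as a block, counts were 6144, 10401, 9639 and 11490. Deviations of same-numbered arrays correlated at 0.19, -0.35 and 0.28 between the intestinal groups, with no common direction. With so few arrays, these values cannot tell whether the numbers pair the samples. Signal over background limits dim genes most on the MHCIIlo arrays.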

Other observations

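The tests of overall signal, of exchanged labels, of lymphoid cells and of kidney levels against intestinal floors were chosen only after their results were seen; the others were set out before. Between the intestinal groups, Toll-like and innate receptor genes differed in both directions, with 6 higher and 4 lower in MHCIIhi of 21 above background, also adjusted over the list alone (camera adjusted p = 0.966). Cd14, a co-receptor for bacterial lipopolysaccharide, was higher by 1.59 ± 0.23 (1.31 within the shared slide), whereas Tlr5 and Naip5, which sense flagellin, differed by -1.88 ± 0.44 and -1.85 ± 0.43 (-1.06 and -1.02 within the slide, where both calls were lost). The transcription factor genes Foxa2 (at least 7.23-fold, measured on 2 of 3 MHCIIlo arrays), Sox9 (2.02 ± 0.28) and Myc (3.28 ± 0.27) were higher in MHCIIhi and kept their calls within the slide (2.38, 1.75 and 3.01). Of 14 villus tip genes, 4 were lower and 0 higher, also adjusted over the list alone (1 higher at unadjusted p under 0.05 in limma), with the keratin gene Krt20 at -1.54 ± 0.31 and Klf4, a transcription factor, at -1.39 ± 0.33 (-0.82 and -0.88 within the slide, both not called; camera adjusted p = 0.164). Acot1, an acyl-CoA thioesterase, was higher by 3.85 ± 0.55 and Cd36, a fatty acid translocase, lower by -2.55 ± 0.39, and both kept their calls within the slide (3.48 and -1.95). Slpi, a secreted protease inhibitor, was 48.5-fold lower in MHCIIhi (limma adjusted p = 0.00312), but 20.5-fold without MHCIIlo 3, 31.1-fold without MHCIIhi 1 and 77.8-fold without MHCIIlo 2 (log2 difference -5.39 within the slide, where the call was lost). None of 18 tuft cell genes was called by limma (0 higher and 0 lower, and 1 and 1 at unadjusted p under 0.05).

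In kidney, 7 of 18 claudin genes were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.355). Cldn10 and Cldn16, tight junction proteins of the loop of Henle, were at least 302-fold and at least 61.7-fold higher. Of 21 Toll-like and innate receptor genes, 3 were higher and 12 lower, also adjusted over the list alone (median -1.54, camera adjusted p = 0.00410; adjusted p = 0.301 with an estimated correlation), and the inflammasome gene Naip5 differed by -9.05 ± 0.37, while Nlrc4 was at least 371-fold lower, measured on 1 of 3 kidney arrays. Of 25 xenobiotic metabolism genes, 18 were lower and 6 higher, also adjusted over the list alone (median -3.85, or -3.51 at the bound; camera adjusted p = 0.00112; adjusted p = 0.321 with an estimated correlation), with the cytochrome P450 gene Cyp2c65 at least 649-fold lower. With genes well above background on all arrays only, that list was not called (adjusted p = 0.148, in a range of 0.000223 to 0.321 over the alternatives). Gcgr, the glucagon receptor, was at least 577-fold higher in kidney, measured on 2 of 3 MHCIIlo arrays.

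The first pattern is that class II transcripts were not higher in the group sorted for high surface MHC class II. The choice among quantile, median, normexp and value-table scaling is argued against as the cause. Under each, 0 of 10 class II genes were called higher in MHCIIhi, and limma called 1, 3, 2 and 3 of them lower. All 4 scale an array to its own signal, so they cannot show a shift that such scaling removes. Overall signal stays open: scaled to the spike-in controls the list median was 1.09, but that scaling adds 1.74 to every gene and the median of all genes was then 1.504, so it decides nothing. Exchanged labels also stay open, as 3 of the 10 genes were called higher in MHCIIlo and transcript and surface protein need not move together. Fewer B cells, macrophages or dendritic cells in MHCIIhi, which the CD45 gate would mostly remove, may also account for the pattern. Protein retained at the surface may do so as well, but the share of either in the class II signal was not tested. The B cell and plasma cell list had 4 members lower and 0 higher in MHCIIhi, and the macrophage and dendritic cell list 6 and 2. Those 4 were Jchain, Mzb1, Pou2af1 and Derl3, without the list member Ms4a1. This count thus cannot tell B cells from antibody-secreting cells.

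The second pattern is the higher level of lymphocyte transcripts in MHCIIlo. Of the members higher there, 93.8% (15 of 16) were well above background on all MHCIIlo arrays. For these 15 the MHCIIlo values were thus measured signals and not the higher floor of the dimmer MHCIIlo arrays. The share itself decides nothing, as only members called higher in MHCIIlo were counted. Lymphoid or plasma cells carried through the sort may be a source, since 57.1% of the 28 T cell and B cell list members tested (16, against 1 higher in MHCIIhi) were higher in MHCIIlo, with Jchain at 4.83 ± 0.43 and Gzma at 1.74 ± 0.51 (SD, n = 3 each). The CD45 gate would remove such cells where they stain for CD45, but how plasma cells stained was not measured. Ptprc was called only without MHCIIhi 1 (-1.37). Of the 28 members, 25 were also well above background on all MHCIIhi arrays, and 1 stands in another list. Of 16 genes with names starting with Igh, Igk or Igl, 15 were also higher in MHCIIlo and 0 in MHCIIhi. Their median for MHCIIhi minus MHCIIlo was -4.94, or -4.52 with unmeasured arrays at their bound. These values do not tell which cells made the transcripts. Expression by the epithelial cells themselves was not tested for these genes or for the list members, and stays open.

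The third pattern is the higher level of endothelial transcripts in kidney. Lower background of the kidney arrays is argued against, because for 18 of 18 members (100%) the lowest kidney array lay above the highest floor of the intestinal arrays (-3.43); that 100% of the called members were well above background in kidney decides nothing, as 10 passed the filter through kidney alone. Endothelial cells carried through the kidney sort may be a source: the list median was -0.85 in kidney 1 relative to the mean of kidney 2 and 3, where Epcam was higher by 1.003, and Emcn (4.30) and Kdr (3.10) were clearly measured. Kidney 1 also differed in other lists, such as enterocyte (1.72) and macrophage (-0.95) genes, the Epcam gate would remove such cells, 8 of the 18 list genes were well above background on all arrays of an intestinal group and 10 on at least 1 intestinal array, and 1 stands in another list. Expression by Epcam-positive kidney cells stays open. So do the slide, which held kidney alone, and the release of the cells, with enzymes for kidney and EDTA for intestine.

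Other splits of the arrays were counted with limma. For MHCIIhi against MHCIIlo, 1 of 10 splits, the real one, gave as many genes (6197; highest other 3, or 2937 at unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. The same holds for kidney against MHCIIhi (1 of 10; 9681; highest other 0, or 236 unadjusted) and kidney against MHCIIlo (1 of 10; 11516; highest other 0, or 214 unadjusted). For kidney against intestine, 1 of 84 splits, the real one, reached the count of 9661 in a fit of 2 groups, a share under 0.05. A split that mixes kidney with intestinal arrays was bound to call fewer genes, as the organs differ most. The share thus does not exclude chance. The arrays come from 3 known groups, so the splits are not all alike. None of them separates organ from slide or from the release of the cells. The highest other was 4670, with MHCIIlo as the group of 3.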
